A study of Diospyros lotus with 24 samples.

How the data were processed

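Buds of the dioecious persimmon Diospyros lotus were profiled in trees of the KK family, the offspring of a cross between a male and a female tree of the cultivar Kunsenshi, and in those parents. The labels assign 20 bud mRNA libraries to 10 male and 10 female trees, with 9 progeny and 1 parent of each sex. They also list bud small RNA libraries and flower small RNA libraries, 1 of each kind per parent. Per the labels, buds were collected on June 17 and July 4 of 2013. The labels place these dates at the early stages of male and female primordia, respectively, and do not say which library came from which date. On 1 reading the male trees were sampled on the first date and the female trees on the second, and date and sex would then coincide in every library. Each tree is a separate individual of its sex, so p-values between the sexes measure the spread between trees, with 1 library per tree.

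Per the labels' protocols, mRNA was purified from total RNA and copied by random priming, and small RNA was concentrated on columns and made into libraries with 12 PCR cycles. The authors deposited whole-number read counts per de novo assembled contig, in 1 column per library, for 417827 contigs with mRNA and 421126 contigs with small RNA. All 417827 contigs of the mRNA table are in the small RNA table. The submitters' processing notes name BWA, R 3.0.1 and DESeq 1.14. The counting rule, the treatment of reads with several matches, read length limits and strand are not given in the sources used here. Contig lengths, deposited beside the small RNA counts, ran from 200 to 21792 bases with a median of 309.0. The files do not pair contigs with gene names, and 0 contig IDs matched a table of 27971 annotated genes of assembly ASM1463336v1. Gene lists fixed for floral, sex-determination and small RNA pathway genes could therefore not be applied. Flower small RNA (2 libraries) was not analysed here.

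Counts between the sexes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr by sex, TMM factors, robust quasi-likelihood fits, and Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter, at least 50 counts in at least 10 libraries, glmTreat against a fold of 2, progeny only, 2 surrogate variables (sva 3.50.0), generation (parent or progeny) or the score on the second principal component as a term, and leave-one-out fits. On counts simulated for 60996 contigs of the 20 libraries, the fit recovered 47% of contigs changed 2-fold and 84% of those changed 4-fold, with 2.24% of its calls false. For the 63600 contigs of 19 libraries these shares were 57%, 89% and 5.19%. The simulated spread between libraries followed the mean level of a contig alone, with no difference between parents and progeny. The shares may therefore not hold for the real libraries.

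A contig was counted as sex-limited when it had at least 3 counts in at least 9 of the 10 libraries of a sex and 0 counts in all 10 of the other. This rule found 200 of 200 contigs planted in simulated data at a mean of 20 counts per male library. The planted contigs had 0 counts in females and counting error alone in males. Their recovery was therefore near certain and does not measure sensitivity at lower counts or with spread between trees. Small RNA features needed at least 10 counts over both parents and a ratio of CPM, counts scaled to a common library total, of at least 4 either way. With 1 library per sex no test was made, and intervals are exact 95% Poisson limits of counts or exact conditional limits of ratios. Reads were not counted by molecular identifiers, so intervals and floors cover counting error only. In simulated small RNA counts the rule found 200 of 200 planted features, and counting error alone made 1862 further calls among 170305 features, of which 0 had at least 50 counts. The median mRNA change of small RNA contigs was placed among 10000 random sets matched on mean mRNA CPM in 50 bins. In simulated data a set of 300 contigs raised by 0.5 lay at the 100th percentile, and at 9.58 before it was raised. That shift is far larger than the mRNA shifts reported here, so it does not show how well small shifts are detected.

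Rules, tests and the named-contig rule were fixed before the data were examined. The rule names at most 2 contigs higher in males and 2 higher in females by p-value, the sex-limited contigs of highest mean count, and the small RNA features of highest count among those that pass. Male replicate 5 held 387 counts. Fits without it were added after seeing the data. Means ± SD of CPM in males leave it out, because a count of 0 in it allows up to 7752 CPM (3 counts). Correlations between libraries used log2(CPM + 0.5) of 62670 contigs with a mean count over 10. In no pair of the other 19 libraries were the counts within sampling noise: the closest pair had a mean chi-square of 3.27 per contig over 63463 contigs. Permutation tests used scipy 1.17.1 and are two-sided unless stated.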

Results

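Bud mRNA was counted on 417827 contigs in 10 male and 10 female trees of Diospyros lotus, and bud small RNA on 421126 contigs in the male and female parent. In 19 of the 20 mRNA libraries the total ran from 3527282 to 15314430 counts, with a median of 6707373. Male replicate 5 held 387 counts on 224 contigs. The other 9 male libraries averaged 8165873 ± 2835194 (SD, n = 9) and the 10 female libraries 5499889 ± 1131782 (SD, n = 10). The means differed (exact permutation test, p = 0.00158) by less than 1 SD of the male libraries. Small RNA totals were 19315399 counts in the female parent and 14168901 in the male parent.

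**Figure D1:**
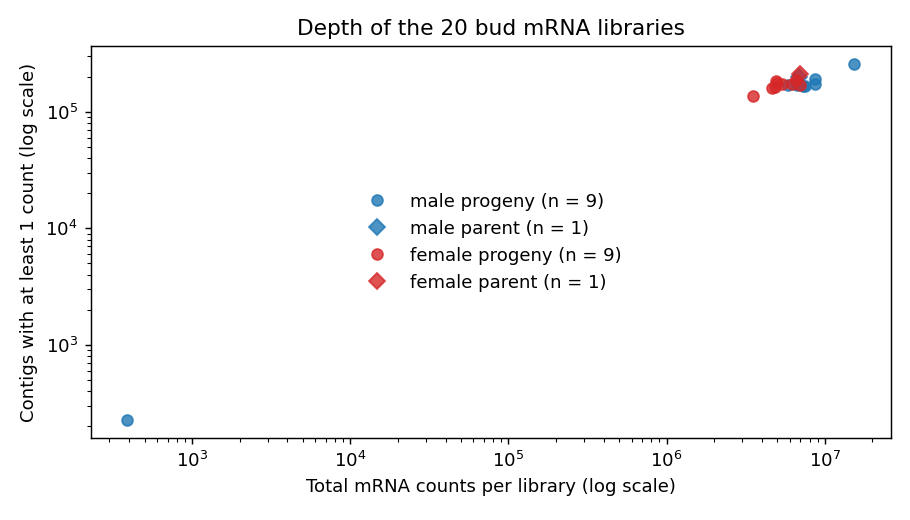
Contigs with at least 1 count against total mRNA counts, both on log scales, for each of the 20 bud libraries; circles are progeny and diamonds parents, blue male and red female. Male replicate 5 sits alone at 387 counts, and the other 19 libraries lie between 3527282 and 15314430.

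The first question was whether libraries of a sex resemble each other across the whole transcriptome. Log2 CPM correlated at 0.910 between progeny of the same sex and at 0.908 between progeny of different sexes, and this gap did not exceed that of other assignments of sex to the 17 usable progeny (one-sided exact permutation test, p = 0.121). The parents stood apart from their progeny, at a mean correlation of 0.813 (34 pairs), and correlated at 0.918 with each other. The first principal component of the 19 usable libraries, 23.5% of the variance, did not differ between the sexes (exact permutation test, p = 0.656, adjusted p = 0.875). It set the female and male parent (scores 0.659 and 0.601) apart from the progeny (-0.222 to 0.139). With 1 parent in each sex, the test on it could hardly find a sex difference. The second component, 11.4%, had p = 0.0337, or 0.135 when adjusted over the 4 components tested. On it 7 of 9 daughters and 2 of 8 usable sons scored above 0, and both parents below 0.

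The mRNA comparison asked which transcripts differ between male and female buds in a species whose males are XY. Few did: 20 of 60996 contigs changed, 3 higher in males and 17 higher in females. The count moved with single libraries: it was 10 to 13, with 1 or 2 higher in males, without any of male replicates 1, 2, 3, 4, 6, 7, 8 or 9, and 31 without female replicate 10. Leaving out any female library gave 6 to 9 contigs higher in males. The smaller sex then had 9 libraries, so the count filter no longer removed contigs counted in the 9 usable males alone. Of these, the 4 added without male replicate 5 (below) were each tested in 11 of the 20 leave-one-out fits. This rise therefore came through the filter and does not show that the calls depend on single female trees. Of the 20 contigs, 11 lacked the call in at least 1 such fit. The count was 32 in progeny alone (3 higher in males), 38 with generation (parent or progeny) as a term (6 higher in males) and 46 with 2 surrogate variables (2 higher in males). With 2 surrogate variables and without male replicate 5 it was 24 (8 higher in males). The contigs higher in males included the largest differences, and those higher in females were moderate in size. Contig202197DeNovoAssembly, 4460 bases long, had 26.4 ± 6.33 CPM in males (SD, n = 9) and 0.616 ± 0.590 CPM in females (SD, n = 10). Its log2 fold change was 5.28 with an SE of 0.35 (edgeR adjusted p = 5.3e-09). Contig217628DeNovoAssembly, 1168 bases long, had 7.74 ± 2.16 CPM in males and 0.311 ± 0.458 in females, a log2 fold change of 4.60 with an SE of 0.39 (edgeR adjusted p = 1.94e-07). For both, each of the 9 usable male libraries exceeded all 10 female ones. The filter removed Contig217628DeNovoAssembly from 8 of the 20 leave-one-out fits. The third contig higher in males, Contig191907DeNovoAssembly, named after its values were seen, had a log2 fold change of 1.32 with an SE of 0.24 (edgeR adjusted p = 0.0351). Over 7 other fits its log2 fold change was 1.28 to 1.44 and its adjusted p 0.000563 to 0.161, past the threshold of 0.05 with limma-voom (0.0524) and with 2 surrogate variables in edgeR (0.161). The highest adjusted p in leave-one-out fits of edgeR was 0.110.

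Among contigs higher in females, Contig196904DeNovoAssembly, 4329 bases long, had 41.0 ± 8.51 CPM in females (SD, n = 10) and 15.0 ± 3.52 CPM in males (SD, n = 9). Its log2 fold change, male over female, was -1.45 with an SE of 0.16 (edgeR adjusted p = 2.69e-05). Contig314662DeNovoAssembly, 2331 bases long, had 70.0 ± 17.2 CPM in females and 28.5 ± 4.64 in males, a log2 fold change of -1.32 with an SE of 0.15 (edgeR adjusted p = 7.5e-05). The remaining 15 contigs, 311 to 8155 bases long, were like these in size of change: over all 17 contigs, log2 fold changes ran from -0.85 to -1.63, at mean female levels of 4.47 to 70.0 CPM. In 6 of the 17 every female library exceeded every usable male library. Over all 60996 contigs tested this held for 6, where chance gives 0.00108% or 0.660 contigs.

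The test called 2836 contigs at an unadjusted p under 0.05, where 3050 would be expected with no difference in any contig. The labels tie no library to either sampling date, and a date that differed between the sexes is not excluded. Without male replicate 5, 22 of 63600 contigs were called, 7 higher in males and 15 higher in females, 18 of them shared with the 20 above. With the score on the second component as a further term 12 were called, 6 in each direction. The 4 contigs added averaged 2.86 to 34.1 CPM in males and had 0 to 13 counts over all 10 female libraries (edgeR adjusted p at most 3.33e-06). They had been removed by the count filter in the fit of 20 libraries. Without any filter 136 contigs were called, 72 higher in males.

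**Figure D2:**
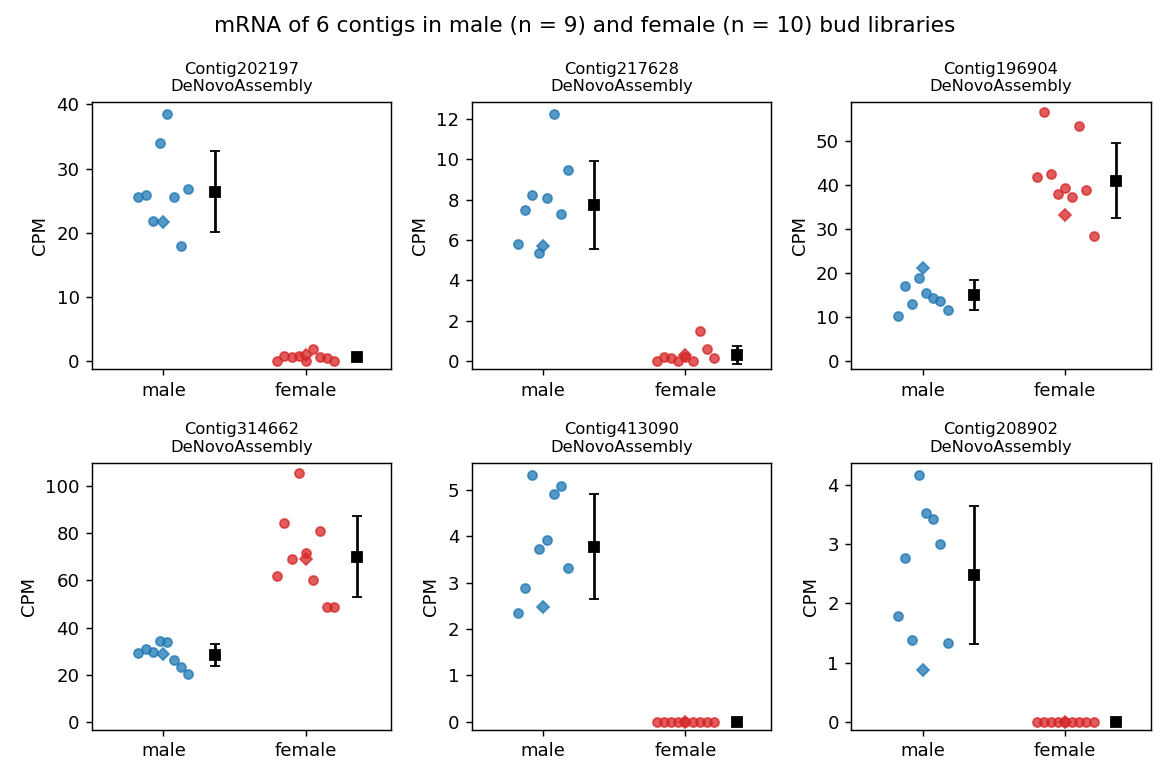
mRNA level in CPM of 6 contigs in each usable library, male (blue, n = 9) and female (red, n = 10), with circles for progeny, diamonds for parents and black squares with bars for mean ± SD. The first 2 contigs are higher in males, the next 2 are higher in females, and the last 2 had 0 counts in every female library.

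A male XY system raises the question of whether some transcripts are counted in males alone. There were 4 such contigs and 0 limited to females. Contig413090DeNovoAssembly, 350 bases long, had 17 to 60 counts in each of the 9 usable male libraries, or 3.78 ± 1.13 CPM (SD, n = 9), at least 69.3-fold higher than the 3 counts that 0 in all female libraries allows (0.0545 CPM over the group). Contig208902DeNovoAssembly, 916 bases long, had 6 to 54 counts, or 2.47 ± 1.16 CPM, at least 45.4-fold higher than that floor. The others, of 502 and 1570 bases, averaged 16.7 and 10 counts per usable male library. Without the parents the same rule gave 7 male-limited contigs and 0 female-limited ones. A rule of at least 1 or at least 10 counts in all 10 libraries gave 0, because male replicate 5 has 0 counts on these contigs. Leaving out any usable male library gave 0 where 9 libraries were still required. Where 1 library could be missing, the count was 7 without male replicate 5 or male replicate 10, and 4 or 5 without any other library.

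The series concerns a small RNA from the Y chromosome, and the parents' bud small RNA was compared to see which contigs carry more of it in a given sex. Of 169824 contigs with at least 10 counts, 2918 (1.72%) had at least 4 times the CPM in the male parent and 3521 (2.07%) at least 4 times in the female parent. These values have no replicate check. The feature with the most counts higher in the male parent, Contig229731DeNovoAssembly of 247 bases, had 38299 counts against 11545, a ratio of 4.52 (95% interval 4.43 to 4.62). Contig165247DeNovoAssembly of 290 bases had 22969 against 3170, a ratio of 9.88 (9.52 to 10.3). On the female side, Contig395402DeNovoAssembly of 872 bases had 27164 counts in the female parent against 4050, a ratio of 4.92 (95% interval 4.76 to 5.09). Contig116950DeNovoAssembly of 993 bases had 18461 against 1784, a ratio of 7.59 (7.23 to 7.97). Over the 5 features of highest count on each side the ratio ran from 4.24 to 9.88 for the male parent and from 4.92 to 7.59 for the female parent. Of these, 3 and 1 were abundant enough for the mRNA test and 0 were called. With at least 50 counts, 490 and 553 of 62222 contigs passed the ratio rule, and in simulated counts 1862 calls came from counting error alone at the lower minimum.

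Small RNA and mRNA differences between the sexes were then set side by side, since a small RNA from males would be of interest where mRNA differs. None of the 20 contigs with changed mRNA was among those with a 4-fold small RNA difference: 0 in the male-higher set and 0 in the female-higher set. Only 1.94% of the contigs tested for mRNA passed the small RNA rule, so 0.389 of the 20 would be there by chance, and the count of 0 does not differ detectably from that. The 805 testable contigs with more small RNA in the male parent had a median mRNA log2 fold change, male over female, of 0.01, against -0.01 in matched random sets. That median lay at the 98.955th percentile of the random sets, which describes these libraries only. It lay at the 100th percentile for the 5291 contigs with a ratio of at least 2 and at 99.73 without male replicate 5. It lay at 85.3 in progeny alone, at 93.2 in the parents' own libraries and at 15.1 with at least 50 small RNA counts, where the median of -0.03 over 117 contigs was inside the random range of -0.05 to 0.03. The 381 testable contigs with more small RNA in the female parent had a median of -0.003, at the 89.9th percentile.

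Contigs whose mRNA was counted almost only in males carried small RNA in both parents. Of 10 contigs with at least 3 counts in each of the 9 usable male libraries and at most 5% of summed CPM in females, a limit set after seeing the data, 10 had small RNA counts in the female parent. Those counts ran from 2 to 248 per contig. Over all 421126 contigs, 326195 had a count in the female parent, so a count there does not set the 10 apart. Together the 10 contigs held 960 small RNA counts in the male parent and 685 in the female parent, a female over male CPM ratio of 0.523 (95% interval 0.474 to 0.578). That ratio rests on 2 contigs, of 590 and 835 bases, which held 762 and 447 of these counts, a ratio of 0.430 (0.382 to 0.484). The other 8 held 198 and 238, a ratio of 0.882 (0.727 to 1.07). The contigs were parted by whether their own interval spans 1, as it does for the 8. A pooled ratio near 1 for the 8 follows largely from that choice. Of their counts, 154 and 185 lay on Contig202197DeNovoAssembly. The mRNA counts of the parents on the 10 contigs were 552 and 11. The 4 male-limited contigs held 12 and 25 small RNA counts.

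**Figure D3:**
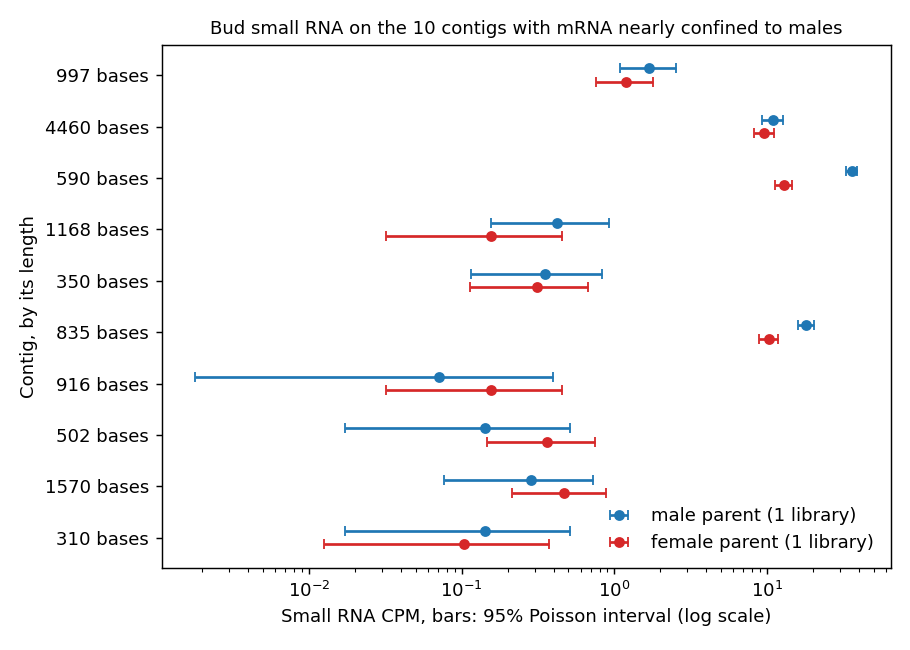
Small RNA level in CPM, on a log scale, of the 10 contigs with mRNA nearly confined to males, given by contig length in bases; blue is the male and red the female parent, and bars are exact 95% Poisson intervals of 1 library each. The intervals of both parents overlap on most contigs, and the 590-base contig had 507 counts in the male parent against 248 in the female parent.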

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

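The measures given here were compared library by library in groups of 10 by a criterion fixed before the data were examined, which chance meets in about 1 of 20 groups; 20 groups were examined and 10 values met it. No explanation was tested for these values.

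Male replicate 5 lay far from the other male libraries in 3 measures of the whole library. It had 224 contigs with a count, where the others had 166898 to 259335. Its 10 most counted contigs took 12.1% of all counts, against 0.952% to 5.78%. Its mean correlation with the usable progeny was 0.0596, against 0.820 to 0.925. It also stood at 0 CPM for Contig196904DeNovoAssembly, where the other males had 10.2 to 21.2 CPM, and at 0 CPM for Contig314662DeNovoAssembly, where they had 20.4 to 34.4 CPM. A count of 0 in that library allows up to 7752 CPM, so these zeros carry no information on the level.

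The female parent (female replicate 10) stood apart from the female progeny. Its 10 most counted contigs took 4.48% of counts, against 1.04% to 1.96%, and its mean correlation with the usable progeny was 0.805, against 0.889 to 0.916. This was not particular to the female parent. In the male parent the values were 5.78% and 0.820, against 0.952% to 1.42% and 0.905 to 0.925 in the usable sons. The criterion looks at the extreme values of a group, and male replicate 5 was the extreme in both measures. The male parent had 3.95 CPM for a 1570-base male-limited contig, where the other usable males had 0.447 to 1.44 CPM. Among females, replicate 6 had 1.94 CPM for Contig202197DeNovoAssembly, against 0 to 1.01 CPM, and replicate 7 had 1.504 CPM for Contig217628DeNovoAssembly, against 0 to 0.620 CPM. These female values stay below every usable male library, whose lowest values were 17.9 and 5.36 CPM.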

How the results depend on the processing

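Settings without male replicate 5, generation (parent or progeny) or the second principal component as a term, the leave-one-out form of the sex-limited count, the parents' own mRNA and the joint small RNA setting were added after seeing the data. The 20 contigs changed between the sexes became 136 without a filter (72 higher in males), 13 with the stricter filter, 32 in progeny alone, 2 against a fold of 2, 46 with 2 surrogate variables, 38 with generation as a term (32 without male replicate 5), 12 with the second principal component as a term without male replicate 5 and 60 with DESeq2 without male replicate 5. The stricter filter excludes contigs counted in 9 males alone by construction; for the others the cause was not tested. The other 9 alternatives gave 16 to 30 contigs, among them 24 with 2 surrogate variables without male replicate 5. Leave-one-out fits gave 10 to 31: leaving out any of male replicates 1, 2, 3, 4, 6, 7, 8 or 9 gave 10 to 13, and leaving out female replicate 10 gave 31. All 4 named contigs kept their direction and call with DESeq2, with library totals alone, in progeny alone and without male replicate 5, except that Contig217628DeNovoAssembly was removed by the filter in progeny alone. Of the 20 contigs, 11 lacked the call in at least 1 leave-one-out fit, among them Contig217628DeNovoAssembly, which the filter removed from 8 of the 20 fits.

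The 4 male-limited contigs became 0 with at least 1 or at least 10 counts in all 10 libraries, since male replicate 5 has 0 counts there, and 7 in progeny alone with or without it. Without that library the count was 11 for at least 1 count and 2 for at least 10 counts in every male library. Allowing 1% of summed CPM in females gave 21, since 1 count in male replicate 5 outweighs all other libraries on this scale, and 6 without it. Leave-one-out gave 0 to 5 where 9 libraries were required, and 4 to 7 where 1 library may be missing; the second form was adopted after the first had been seen to return 0 whenever a usable male was left out. Female-limited contigs numbered 0 in every setting.

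The 6439 small RNA features became 1043 at 50 counts and 34064 at a ratio of 2, as the rules imply. For mRNA of contigs with more small RNA in the male parent, the 98.955th percentile became 100 at a ratio of 2, 99.73 without male replicate 5, 85.3 in progeny alone, 93.2 in the parents' own libraries and 15.1 at 50 counts, where the median changed side within the random range; the cause was not tested. Gene lists and flower small RNA were not run. No paired analysis was possible because replicate numbers are only names. Depth limits male-limited calls to contigs of about 3 counts per library.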

Other observations

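The tests in this part were chosen after the results they bear on had been seen, except the splits of the libraries for sex-limited contigs, and the 5% limit used to define contigs nearly confined to males was likewise set after seeing the data. The bound for contigs that stay called with the second principal component as a term was set before that count was seen, though after the calls themselves.

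The 2 parents differed from their progeny in far more transcripts than the sexes did. With sex in the model, 10306 of 63600 contigs were higher and 8694 lower in the 2 parents than in the 17 usable progeny (edgeR, adjusted p under 0.05), which is 29.9% of those tested. Differences of at least 4-fold numbered 1229 higher and 804 lower. Among the most abundant, Contig305234DeNovoAssembly rose by 3.99 on the log2 scale in parents (SE 0.33, edgeR adjusted p = 2.54e-07) and Contig258875DeNovoAssembly by 3.49 (SE 0.34, edgeR adjusted p = 1.39e-06), while Contig73303DeNovoAssembly fell by 3.27 (SE 0.69, edgeR adjusted p = 0.00196). Each parent is 1 tree, so these values describe those trees.

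Besides the male-limited contigs, others were nearly confined to males. In all, 10 contigs had at least 3 counts in each of the 9 usable male libraries and at most 5% of their summed CPM in females. They held 6701 counts in males and 74 in females, and the female share of counts per contig ran from 0 to 2.73%. The most abundant, a contig of 997 bases chosen after its values were seen, had 135 to 483 counts in males and at most 3 in any female library, at 34.1 ± 14.1 CPM (SD, n = 9) against 0.248 ± 0.201 (SD, n = 10).

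The first pattern weighed was the set of contigs changed between the sexes. Of 100 splits of the 20 libraries, 1, the real one, gave as many as 20 contigs, and the highest other gave 1. A random split thus rarely gave so many. These splits are a small draw from all possible ones, and splits along a structure of the samples may be missed by it. Without male replicate 5, 2 of 100 splits gave at least 22 contigs, the real one included. The other gave 161, with both parents and 7 daughters against 8 sons and 2 daughters, and so large a count points to a structure of the samples. All 3 other splits with any contig had both parents on 1 side, as had 54 splits with 0 contigs, and all 42 other splits with the parents apart, as in the real one, gave 0. All 7 of those daughters scored above 0 on the second principal component, and 8 of the 10 progeny on the other side below 0. The split of 161 gave 203 contigs with generation (parent or progeny) as a term, 1090 with the score on that component as a term and 0 with both. The real split gave 32, 12 and 21. For the split of 161, the 2 terms together overlap closely with the split itself and leave little of it to test. The count of 0 may follow from that overlap alone, so it does not show what those calls went with. What the component stands for is not known, and it runs partly along sex, with 7 of 9 daughters above 0 and 6 of 8 usable sons below 0. With its score as a term 12 of the 22 contigs stayed called, which argues against this axis as the cause for those 12. The call ended for the other 10, 9 of them higher in females: their median size of log2 fold change was 1.15 (median SE 0.20) before and 1.19 (median SE 0.23) after, and their adjusted p was 0.0543 to 0.460. The fold changes of those 10 did not shrink on balance, and each of the 22 contigs kept at least 0.678 of its log2 fold change. These values do not settle whether the axis is the source of the differences in the 10 contigs. Its score was computed from the same counts and coincides in part with sex. The calls of the 10 did not survive the added term, so a sex difference in each single contig stays open. Sampling date and sex cannot be told apart, because 0 libraries have a date of their own in the labels, and the 2 dates are given for male and female stages, respectively, so the sexes may have been sampled on different dates.

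The second pattern was the 4 male-limited contigs. No other of 100 splits gave any (1 split as large, highest other 0), so a random split of the libraries rarely gives such contigs. At the male CPM, 527 counts were expected in females over the 4 contigs, at least 66.9 for each, so lower depth alone would hardly leave 0. The rule itself set the 0 in females and at least 3 counts in each usable male library. A large expected count was thus largely fixed by the choice of contigs, and the comparison is not a separate test of depth. A hypothesis is that these sequences may be inherited from the father alone, as a Y-linked sequence would be. There were 7 contigs with at least 3 counts in all 8 usable sons and 0 in all 9 daughters. Of these, 4 had at least 3 counts in the father, the other 3 had 1 or 2 counts there, and 0 had counts in the mother. The father is male and the mother female, so a transcript made in males alone would give the same counts however inherited. The parents therefore cannot decide the hypothesis, which stays open. The opposite pattern of daughters without sons was shown by 0 contigs.

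The third pattern was small RNA on contigs nearly confined to males, which the female parent carried as well. Over the 10 contigs it had 685 small RNA counts against 960 in the male parent, while its mRNA counts were 11 against 552. Reads crossing over from the male library would leave at most 0.271% of male counts, the upper limit for a contig with 5 counts against 4309, and the female counts were 71.4% of the male ones. Fragments of mRNA in the same tree would give the mRNA ratio of 0.0197 (95% interval 0.00977 to 0.0355), and the small RNA ratio, female over male CPM, was 0.523 (0.474 to 0.578). The contigs were chosen for little mRNA in females, the female parent included. A low mRNA ratio thus follows in part from that choice, which its interval does not cover. The pooled small RNA ratio does not describe each contig. Parted by whether a contig's own interval spans 1, it was 0.430 (0.382 to 0.484) over 2 contigs with 762 of the 960 male counts and 0.882 (0.727 to 1.07) over the other 8. That way of parting itself largely sets a ratio near 1 for the 8. The upper limits of the mRNA ratio in these 2 parts, 0.0772 and 0.0390, lay below both small RNA ratios. Reads of similar sequences elsewhere in the genome could be the source and cannot be told apart from small RNA of the contigs themselves, since no contig sequence was used and 8 of the 10 contigs had a ratio whose interval spans 1.

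A further hypothesis concerned contigs that are on in some progeny and off in others. Of contigs with either 0 or at least 3 counts in each of the 17 usable progeny, 444 were on in 5 to 12 of them, in 242 patterns. The pattern of sex held 7 contigs, 6 patterns held more, and the largest held 27; in 100 shuffles the largest pattern held at most 2 and the pattern of sex 0. Such contigs may be inherited from 1 parent. Of the 437 outside the pattern of sex, 60 were taken whose patterns differed in at least 4 progeny from each other and from each other's mirror, with 0 or at least 3 counts in each parent. Of these, 39 were counted in 1 parent alone, 15 in both and 6 in neither. Shuffling the mother's state among contigs on in as many progeny gave 21 to 35 in 1 parent alone (95% of 10000 shuffles, one-sided permutation p = 0.002). In the pattern of 27 contigs, 22 had at least 3 counts in the mother and 0 in the father. Other contigs went against it: 85 of the 437 had at least 3 counts in both parents, beside 252 with at least 3 in 1 parent and 0 in the other. In a pattern of 11 contigs, 9 had at least 3 counts in both parents and 0 were counted in 1 parent alone.

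The contigs higher in females could have been those with more small RNA in the male parent, as a silencing small RNA from males would leave them. As a set they did not show it: over the 16 of 17 with at least 10 small RNA counts, the median log2 ratio, male over female, was -0.22, at the 3.15th percentile of matched random sets. The members went both ways, so the question stays open: 6 had a ratio above 1, with the 95% interval above 1 for 3 and below 1 for 4. The ratio was 1.22 (1.07 to 1.39) for Contig196904DeNovoAssembly and 1.40 (1.08 to 1.81) for Contig314662DeNovoAssembly, and the highest was 1.67 (1.10 to 2.55). Small RNA was compared in 1 library per sex over whole contigs, so a change confined to a short stretch of a contig was not tested.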
